A study of Mus musculus with 15 samples.

How the data were processed

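Nasal tissue of BALB/c mice was profiled by RNA sequencing of total RNA in 15 libraries. Per the labels, the groups were non-sensitized mice given saline, mice of an ovalbumin-induced rhinitis model (OVA), and such mice given dexamethasone at 1 mg/kg or Cirsium japonicum extract at 100 or 300 mg/kg. Groups of 6 to 8 mice were formed on day 21, and 3 libraries per group were analysed here. Each library was assigned to its group by the treatment in its labels.

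For each library the authors deposited a gene table with expected counts, which need not be whole, together with TPM and FPKM values, per the file headers. FastQC, Trim Galore, STAR and RSEM and the build mm10 are named in the submitters' processing notes. Their versions, the annotation release, the read length and the strand setting were not given in the sources used here. The expected counts estimated by RSEM share reads between similar genes, so values of close paralogs (Bpifb9a and Bpifb9b, Obp1a and Obp1b, the alpha globins, receptor families) and of overlapping or antisense genes are uncertain. The TPM values deposited by the authors were used only to check their sum, 1000000 or 1000001 per library, and the FPKM values deposited by the authors were not used. A series-wide table of expected counts deposited by the authors held the same values as the library tables (0 differing) after 1 leftover header line was removed.

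Expected counts of 25239 genes were rounded to whole numbers (1925 to 2301 genes per library had a value that was not whole). Depth was 20899972 to 30359854 expected counts per library (median 25918150), and 3 counts, used as the floor for a gene at 0, equal 0.098 (saline 1) to 0.175 CPM (saline 2) of the effective library size. Vomeronasal receptor sums are CPM of total counts. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. No libraries were near-duplicates: the lowest chi-square per gene between any pair was 52.2 (OVA 2 and CSJ100 2), followed by 52.5 (OVA 2 and OVA 3).

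Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (TMM factors, filterByExpr with a minimum count of 10 and total of 15, robust fitting) on all 15 libraries in 1 fit by group, with 10 residual degrees of freedom and a common coefficient of biological variation of 35%. Benjamini-Hochberg adjustment was applied over the 17873 tested genes of a comparison, and an adjusted p under 0.05 was called. A log2 difference has as SE its absolute value divided by the square root of the F statistic. The comparisons were OVA with saline, DEX, CSJ100 and CSJ300 with OVA, CSJ300 with CSJ100 and with DEX, and a slope over 0, 100 and 300 mg/kg expressed per 100 mg/kg. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

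Named genes followed this rule. Per comparison they are the 10 that rose and the 10 that fell with the smallest p among called genes with a mean of at least 1 CPM and no overlap between both groups, leaving out predicted genes and pseudogenes. If fewer than 5 qualified, the 3 of each direction with the smallest p are named as not passing. From each list up to 4 members passing adjusted over the list alone were eligible, or else up to 2 of highest level. Muc5ac, Muc5b, Clca1, Nfe2l2, Keap1, Hmox1, Nqo1, Il4, Il5, Il13, Fkbp5 and Tsc22d3 were always eligible. The slope and the comparisons of CSJ300 with CSJ100 and DEX name at most 10 genes by p.

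The 32 fixed lists covered inflammatory and tissue responses (type 2 cytokines, IL-13 response, mucins, NRF2, NF-kB, interferon, glucocorticoid, aryl hydrocarbon receptor, junctions, matrix, MHC class II, cell cycle, immediate early genes) and markers of the cell types a nasal dissection could hold. Of 514 list entries, 13 had no entry in the table and 4 were matched by a synonym. The tooth list had no tested member, so 31 lists were tested. Camera (limma 3.58.1, preset correlation 0.01, prior count 2), camera with an estimated correlation, and fry were run, with Benjamini-Hochberg adjustment over lists. Fry's p tests whether members move, on balance, one way, and compares them with no other genes. In some lists the signs of median, mean and camera test differ, as in nasal gland secretion for CSJ100 (median -0.63, mean 0.67, camera upward) and neutrophil for CSJ300 (median 1.08, mean 0.22, camera downward). Clock gene and nuclear RNA lists were added after the data were seen.

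Alternatives were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom with quality weights, non-robust fitting, no or a stricter filter (CPM of at least 1 in 3 libraries), only the groups compared, the replicate number as a block, covariates for olfactory neuron and skeletal muscle lists, the series-wide table, an added threshold of 1 on the absolute log2 difference, and leaving out each library in turn. A correction for GC content and length (spline with 5 degrees of freedom, available for 98% of tested genes) and covariates for vomeronasal receptor counts and the class I receptor share were added after the data were seen. Class I receptors were taken as the olfactory receptor genes in the chromosome 7 cluster from 102476579 to 105369355. Gene positions come from the GENCODE annotation of mm10, in which 24366 genes of the table were found by symbol.

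Chance values of correlations between comparisons with shared OVA libraries came from 20 simulations of unchanged groups. Other splits of the samples were all 10 for comparisons of 3 with 3 libraries and 100 for the slope. The procedure was tested on simulated data for CSJ300 against OVA with 17696 genes and 50 changed genes per fold size: it recovered 40% of genes changed 2-fold, 80% at 4-fold, 92% at 8-fold and 96% at 16-fold, with 7 false calls among 161. The list test found the changed list and 0 of the others among 31 lists. Simulated genes varied independently of each other, so these runs do not show how gene or list calls hold where genes move together. In the real libraries camera called 8 to 17 lists per comparison with the preset correlation and 0 with an estimated one. A simulated GC trend gave 4521 calls before and 0 after correction. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.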

Results

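RNA sequencing measured gene expression in nasal tissue of BALB/c mice in an ovalbumin model of allergic rhinitis. The 15 libraries fell into 5 groups of 3. They were saline controls, mice given ovalbumin (OVA), and OVA mice treated with dexamethasone at 1 mg/kg (DEX) or with an extract of the thistle Cirsium japonicum at 100 mg/kg (CSJ100) or 300 mg/kg (CSJ300). Dexamethasone is a synthetic glucocorticoid. Expected counts per library summed to 29050998, 22436936 and 22718165 for saline, 29065716, 28416596 and 26432310 for OVA and 25918150, 30359854 and 27194452 for DEX. They summed to 20899972, 25683587 and 22798771 for CSJ100 and 22310672, 22077776 and 26419352 for CSJ300. The table listed 25239 genes, of which 17873 had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these samples. Log2 differences are given with their SE and levels in CPM (counts scaled to the effective library size) with the SD, at n = 3 libraries per group. Gene positions are those of the mouse build mm10.

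The libraries differed in the kind of nasal tissue they held. Olfactory receptors of class I, which are encoded in a cluster on chromosome 7 (102476579 to 105369355; 125 of the 1132 receptor genes counted) and used by neurons of the dorsal olfactory epithelium, took 22.5% ± 4.87 of all olfactory receptor counts in saline, 24.2% ± 4.55 in OVA and 20.8% ± 4.28 in DEX (SD, n = 3). Their share was 10.1% ± 11.2 in CSJ100, where the libraries held 2.99%, 23.1% and 4.29%, and 2.84% ± 1.3 in CSJ300. The CSJ300 share lay below the OVA share in every library (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). Vomeronasal receptor genes, which are used in the vomeronasal organ beside the nasal septum, summed to 251, 558 and 302 CPM of total counts in CSJ300. On that scale they summed to 828, 509 and 1.9 CPM in DEX, 50.9, 2.18 and 1.93 CPM in OVA, 13.4, 2.73 and 4.34 CPM in CSJ100, and 1.67 to 2.89 CPM in saline.

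**Figure D1:**
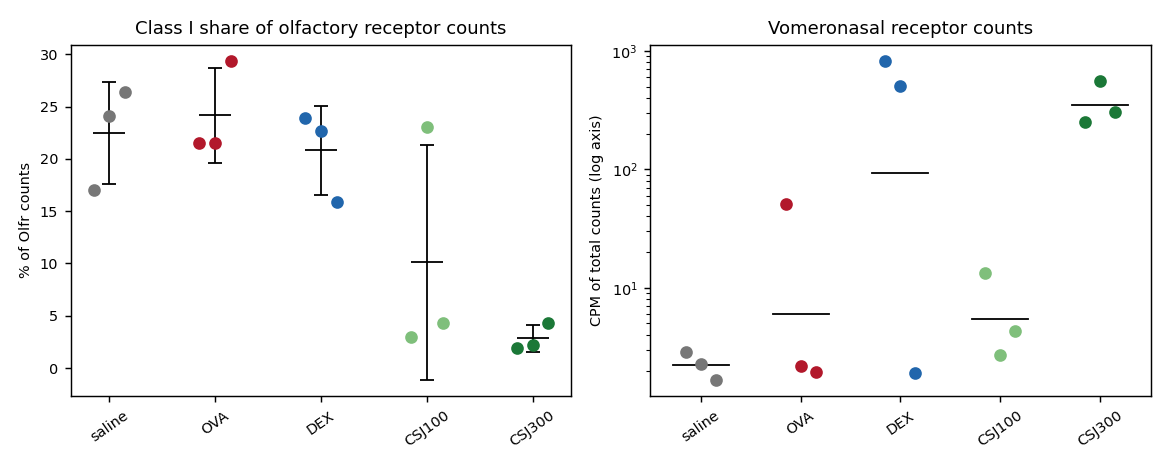
Left panel, share of olfactory receptor counts from class I genes (percent), and right panel, summed vomeronasal receptor counts (CPM of total counts, log axis), each by group; points are libraries, and the line is the mean with its SD on the left and the geometric mean on the right. The 3 CSJ300 libraries lie at 1.94%, 2.24% and 4.33%, below all OVA libraries (21.5% to 29.4%), and vomeronasal counts are above 200 CPM in all CSJ300 libraries and in 2 of 3 DEX libraries.

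The comparison of OVA with saline asked how the allergic model differed from non-sensitized mice. Nr4a3, an orphan nuclear receptor of the immediate early class (chromosome 4, 48045153 to 48086447), fell from 14.6 ± 0.848 CPM in saline to 1.83 ± 0.435 CPM in OVA. It was the only gene called, with a log2 difference of -3.0 ± 0.37. The smallest p-values in the other direction belonged to genes of type 2 inflammation, which did not pass over all genes: Retnla, a resistin-like product of alternatively activated macrophages, differed by 6.00 ± 1.11, and Rnase2a, an eosinophil ribonuclease, by 5.20 ± 0.94. Kirrel2, a neuronal adhesion molecule, followed with a difference of 1.76 ± 0.34. In saline Retnla was at 0.135 CPM and Rnase2a at 0.0694 CPM, near or below the floor of 3 counts (0.098 to 0.175 CPM). The sizes of their differences are therefore uncertain.

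Members of the fixed lists moved in the OVA group as follows. Tissue lists were lower, with medians of -1.58 for squamous epithelium, -1.34 for bone and cartilage, -0.64 for extracellular matrix and -1.40 for erythroid cells. Each had 0 members higher and 0 passing (camera, adjusted p = 0.000569, 3.78e-06, 1.94e-07 and 0.0268, and 0.532 to 0.624 with an estimated correlation). Both groups overlapped in each of these lists. The mean log2 CPM was 1.49 to 6.39 in saline and 1.08 to 4.85 in OVA for squamous epithelium, and 5.24 to 6.31 and 3.63 to 5.92 for bone. It was 5.93 to 6.87 and 5.22 to 6.1 for matrix, and 3.56 to 6.21 and 3.33 to 4.72 for erythroid cells. In the IL-13 and type 2 tissue response list, 0 of 21 members passed over all genes and 2 were higher adjusted over the list alone, Retnla and Ccl8 (3.12 ± 0.83). The mast cell and basophil list had 3 of 13 members higher adjusted over the list alone: the proteases Mcpt1 (7.66 ± 1.91) and Mcpt2 (6.17 ± 1.74) and the IgE receptor chain Fcer1a (2.79 ± 0.89). Their saline levels were 0.0989, 0.227 and 0.0803 CPM, near or below the floor of 3 counts, and Mcpt1 spanned 3.3 to 44.2 CPM in OVA. The sizes of these differences are therefore uncertain. The eosinophil list had a median of 1.77 over 9 members, none of which passed; Prg2, a granule protein, was at 1.89 ± 0.96 and Ear2 at 1.87 ± 0.69. In the immediate early and heat shock list, 3 of 17 members were lower adjusted over the list alone, the transcription factors Jun (-0.77 ± 0.13), Fos (-1.32 ± 0.28) and Egr1 (-1.84 ± 0.39). The gel-forming mucins did not pass, with Muc5ac at 0.86 ± 1.09 and Muc5b at 1.01 ± 0.65, nor did the goblet cell gene Clca1 at 3.01 ± 1.42. Transcripts of the cytokines Il4, Il5 and Il13 lay below the count filter, at no more than 0.633 CPM in any library. For NRF2, the regulator of antioxidant genes, Nfe2l2 was at 0.28 ± 0.17, its inhibitor Keap1 at 0.06 ± 0.11 and its target Nqo1 at 0.47 ± 0.56.

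Nr4a3 had an adjusted p of 0.0498 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 568 genes had an unadjusted p under 0.05, while DESeq2 called 23 genes and limma-voom 6. Camera with a preset correlation called 17 of 31 lists, among them eosinophil (adjusted p = 1.26e-07) and immediate early (adjusted p = 6.19e-09). With an estimated correlation 0 lists passed (adjusted p = 0.532 and 0.239 for these lists), and fry called 0. The Nr4a3 call ended when any one of the 6 libraries (saline 1, 2 or 3, OVA 1, 2 or 3) was left out, and also with RLE factors, with library size alone, with only both groups in the fit, with the replicate number as a block, with the muscle or vomeronasal covariate and with the GC correction.

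The DEX comparison gives the reference drug in the same model. Eosinophil genes had the lowest median of the 31 tested lists (-2.64): Siglecf, a surface lectin of eosinophils (chromosome 7, 43351341 to 43359531), was at 2.45 ± 0.334 CPM in OVA and 0.387 ± 0.255 CPM in DEX. Of the 9 eosinophil list members, 0 passed over all genes and 3 were lower adjusted over the list alone: Siglecf (-2.64 ± 0.51), Prg2 (-4.29 ± 1.09) and the peroxidase Epx (-3.77 ± 1.10). The mean log2 CPM of the list was -2.14, -1.87 and 0.57 in DEX 1, 2 and 3 (1.12 to 2.15 in OVA). The erythroid and marrow precursor list was low in the same libraries, at 0.67, 1.51 and 3.99 (3.33 to 4.72 in OVA), with a median difference of -1.78 and 0 of 11 members passing (camera, adjusted p = 0.000486, and adjusted p = 0.648 with an estimated correlation). Of 21 glucocorticoid response genes, 0 passed over all genes and 6 were higher adjusted over the list alone, among them Map3k6 (2.30 ± 0.70), Angptl4 (2.07 ± 0.65), Zbtb16 (2.16 ± 0.69) and Errfi1 (0.60 ± 0.20). Fkbp5, a classical glucocorticoid target, was at 1.26 ± 0.43 and did not pass over all genes, nor did Tsc22d3 at 0.47 ± 0.49. The mean log2 CPM of the list was 6.39 in DEX 1, 5.11 in DEX 2 and 5.46 in DEX 3 against 4.71 to 5.27 in OVA, so that DEX 2 lay within the OVA range and DEX 1 stood apart. Angptl4 and Zbtb16 overlapped between both groups, with 2.07 to 17.9 and 5.28 to 42.2 CPM in DEX.

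Further groups had members that passed only when adjusted over the list alone. The interferon response list had 7 of 20 higher, including Oas2 (2.22 ± 0.56), Oasl2 (1.51 ± 0.40), Oasl1 (2.32 ± 0.63) and Irf7 (1.85 ± 0.58). Its mean log2 CPM was 1.87, 3.5 and 3.08 in DEX 1, 2 and 3 against 1.91 to 2.25 in OVA, so that DEX 1 lay below all OVA libraries, and Irf7 overlapped between both groups. The fat cell list had 3 of 5 higher, Fabp4 (2.60 ± 0.83), Cidec (3.68 ± 1.18) and Plin4 (2.13 ± 0.86), all genes of lipid storage. Its mean log2 CPM was 2.77, 2.88 and 1.11 in DEX 1, 2 and 3 and -0.55, -1.4 and 1.23 in OVA 1, 2 and 3, so that DEX 3 lay below OVA 3, and Plin4 overlapped between both groups. Cidec was at 0.153 ± 0.237 CPM in OVA, near the floor of 3 counts, so the size of its difference is uncertain. The vomeronasal neuron list had 4 of 8 higher, among them the channel Trpc2 (3.07 ± 0.82) and Calr4 (4.02 ± 1.21), in the group in which DEX 1 and DEX 2 held 828 and 509 CPM of total counts of vomeronasal receptors. The mean log2 CPM of the list was 7.47, 7.27 and 5.6 in DEX 1, 2 and 3 against 6.07 to 6.38 in OVA, so that DEX 3 lay below all OVA libraries, and Trpc2 and Calr4 overlapped between both groups. Cd68 of the macrophage list (0.95 ± 0.26) and Mmp13 of the bone and cartilage list (2.37 ± 0.64) were also higher adjusted over the list alone. The basal and squamous epithelium list had a median of 1.88 with all 16 members higher and 0 passing (camera, adjusted p = 8.77e-05, and 0.648 with an estimated correlation). Its mean log2 CPM was 2.72, 4.22 and 6.37 in DEX 1, 2 and 3 and 1.38, 1.08 and 4.85 in OVA 1, 2 and 3. Without passing over all genes, the smallest p-values belonged to B4galt5 (1.40 ± 0.26), Irak3 (1.20 ± 0.23), Dlx3 (3.07 ± 0.62), Aifm3 (-1.11 ± 0.17), Siglecf and Mybl1 (-1.34 ± 0.26). Muc5ac was at -1.11 ± 1.09, Muc5b at -0.41 ± 0.65, Clca1 at -2.72 ± 1.39 and Nqo1 at -0.21 ± 0.56.

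In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes passed between DEX and OVA (smallest adjusted p = 0.442), 1287 had an unadjusted p under 0.05, DESeq2 called 50 and limma-voom 3010. Camera called 17 of 31 lists with the preset correlation, including eosinophil (adjusted p = 2.55e-09) and glucocorticoid response (adjusted p = 3.38e-06). No list passed with an estimated correlation (adjusted p = 0.545 and 0.648 for these lists) or with fry. Without DEX 3, 40 genes passed (39 higher and 1 lower).

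The extract at 100 mg/kg was compared with OVA at the lower of both doses. Blood vessel genes lay below OVA: of 10 endothelial cell genes, 0 passed over all genes and 6 were lower adjusted over the list alone. They included Tek (-1.59 ± 0.42), Vwf (-1.80 ± 0.50), Cdh5 (-1.56 ± 0.49) and Pecam1 (-0.95 ± 0.30), which encode the angiopoietin receptor, von Willebrand factor and endothelial adhesion proteins. Cdh5 (chromosome 8, 104101625 to 104144511) was at 15.2 ± 1.65 CPM in OVA and 5.15 ± 2.89 CPM in CSJ100. The endothelial list had a median of -1.16, skeletal muscle -3.09 and squamous epithelium -1.98, the last 2 with 0 of 16 members higher. Aryl hydrocarbon receptor (-0.98) and Schwann and myelin (-0.69) genes were lower too, while neutrophil (1.82) and eosinophil (1.56) lists had the highest medians. The muscle list overlapped between both groups, with a mean log2 CPM of 1.42, -0.53 and 4.92 in OVA 1, 2 and 3 and 1, -0.41 and -0.19 in CSJ100. The squamous list overlapped likewise (1.38, 1.08 and 4.85 in OVA, 0.82, 2.34 and 1 in CSJ100). OVA 3 stood highest in both lists. Secretory genes of nasal glands went both ways, with 4 of 19 higher and 1 lower adjusted over the list alone: Odam (5.86 ± 1.26), Bpifb5 (7.67 ± 1.85) and Bpifb9b (8.56 ± 2.70) were higher and Bpifa1 (-1.84 ± 0.52) lower. Bpifb9b has a close paralog, Bpifb9a, with which it could share reads. CSJ100 1 held the highest levels, as Odam was at 34.9 ± 39 CPM in CSJ100 (4.07 to 78.8), Bpifb5 at 343 ± 413 CPM (30.4 to 812) and Bpifb9b at 15400 ± 19000 CPM. Without CSJ100 1 the log2 differences of these genes were 4.42, 6.02 and 6.80.

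Mucin and NRF2 genes of CSJ100 did not pass over all genes. Muc5ac was at -3.31 ± 1.18, Muc5b at -1.21 ± 0.66, Clca1 at -2.31 ± 1.37 and Nqo1 at -0.81 ± 0.57. Osgin1, the only NRF2 list member lower adjusted over the list alone (1 of 33), was at -0.74 ± 0.18, and Ocln was the only one of 16 epithelial junction genes (-0.53 ± 0.14). The smallest p-values over all genes, none passing, belonged to Cabs1 (8.45 ± 1.44), Thoc2 (0.59 ± 0.11), Tmem132a (1.24 ± 0.24), the muscle growth inhibitor Mstn (-3.58 ± 0.62), Rsu1 (-0.64 ± 0.12) and Rbl2 (-0.41 ± 0.08). Cabs1 was at 0.137 ± 0.209 CPM in OVA and Mstn at 0.164 ± 0.174 CPM in CSJ100, near the floor of 3 counts. Cabs1 also spanned 6.14 to 93.3 CPM in CSJ100, and the sizes of both differences are uncertain. Among cell markers, Prg2 of eosinophils was at 1.61 ± 0.93, Kit of mast cells at -0.77 ± 0.42 and Omp of olfactory neurons at 0.66 ± 0.38, and none passed.

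For CSJ100 against OVA, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p = 0.209), with 2987 genes at an unadjusted p under 0.05, while DESeq2 called 577 and limma-voom 2541. Camera called 14 of 31 lists with the preset correlation, including endothelial cell (adjusted p = 3.24e-05), which had an adjusted p of 0.792 with an estimated correlation, as 0 lists passed there and 0 with fry. Without CSJ100 2, the CSJ100 library with a class I receptor share of 23.1%, 1159 genes passed (360 higher and 799 lower).

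At 300 mg/kg the extract group differed from OVA in 1497 genes, of which 488 rose and 1009 fell. Blood vessel genes fell: 7 of 10 endothelial cell genes passed over all genes and 10 adjusted over the list alone, with Tek at -2.57 ± 0.44, Cdh5 at -2.61 ± 0.51, Vwf at -2.44 ± 0.51 and Esam at -1.94 ± 0.45. Cdh5 fell from 15.2 ± 1.65 to 2.49 ± 1.56 CPM, and Ace, the angiotensin-converting enzyme of vessel walls (chromosome 11, 105967945 to 105989964), from 77.2 ± 9.84 to 15.6 ± 3.62 CPM. Schwann cell and myelin genes fell in the same group, 6 of 8 over all genes and 7 adjusted over the list alone, with Sox10 at -1.99 ± 0.46, Mag at -3.09 ± 0.71, Prx at -1.58 ± 0.37 and Mpz at -1.65 ± 0.39. These falls stood beside a class I receptor share of 2.84% and the vomeronasal receptor counts of 251 to 558 CPM of total counts.

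Of 11 aryl hydrocarbon receptor genes, 4 fell over all genes and 8 adjusted over the list alone, with the glucuronosyltransferase Ugt1a7c at -3.70 ± 0.86, Cyp1a1 at -4.43 ± 1.16, Nqo1 at -2.23 ± 0.59 and Ahr itself at -0.88 ± 0.23. With the class I share (2.84% in CSJ300, 24.2% in OVA) as covariate, Cyp1a1 was at 0.25, Nqo1 at 0.18 and Gsta2 of the NRF2 list at 0.01. Their sign changed, but none passed in that fit, where the 1497 called genes had a median SE of 0.587. A difference in the opposite direction is thus not shown. Of 33 genes in the NRF2 list, 4 fell over all genes and 7 adjusted over the list alone: Osgin1 (-0.97 ± 0.18), Gclm (-1.0 ± 0.21), a subunit of the enzyme that starts glutathione synthesis, Gsta2 (-1.76 ± 0.45) and Nqo1. Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206), fell from 376 ± 76.9 to 80.0 ± 8.21 CPM. Nfe2l2, which encodes NRF2, was at -0.09 ± 0.17, Keap1 at -0.04 ± 0.11 and the target Hmox1 at 0.08 ± 0.23, and none passed.

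Among 15 mucin and goblet cell genes, 2 fell over all genes and 3 adjusted over the list alone. Muc15 (-1.46 ± 0.28) and Agr2 (-1.31 ± 0.34), a protein disulfide isomerase needed for mucin assembly, passed over all genes. Agr2 was also the only one of 21 members of the IL-13 response list to pass. Muc5b (chromosome 7, 141839070 to 141873084), at 3560 ± 1130 CPM in OVA and 735 ± 382 CPM in CSJ300, passed only adjusted over the list alone (-2.28 ± 0.68). Muc5ac (-2.87 ± 1.16) and Clca1 (-0.05 ± 1.28) did not pass.

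Of 10 MHC class II genes, 2 rose over all genes, H2-DMb2 (1.57 ± 0.35) and H2-DMb1 (1.89 ± 0.43), and 7 adjusted over the list alone, including H2-Ob (3.80 ± 1.12) and Ciita (2.32 ± 0.70). Pax5, a B cell transcription factor, rose by 3.78 ± 1.03 as 1 of 9 B and plasma cell genes, and 0 of 16 T cell genes passed, with Lck at 2.20 ± 0.85. These 3 lists were high in the same libraries: in CSJ300 1, 2 and 3 the mean log2 CPM was 3.56, 5.18 and 5.61 for MHC class II (2.93 to 3.52 in OVA), 2.48, 4.67 and 5.23 for B and plasma cells (2.53 to 3.25) and -0.76, 1.8 and 2.4 for T cells (-0.37 to 0.22). CSJ300 1 was thus near or below OVA in each. Immediate early genes Jun (0.62 ± 0.13) and Ier2 (0.61 ± 0.15) rose, 2 of 17 in their list, but Ier2 was at -0.09 with the class I share as covariate. Single members passed in other lists: Oas2 of the interferon response (2.11 ± 0.56) and Gng8 of olfactory neurons (1.56 ± 0.43), named after its value was seen, rose. The chemokine Cxcl5 of acute inflammation (-2.77 ± 0.68), Gata2 of mast cells (-2.08 ± 0.49), the water channel Aqp5 of Bowman glands (-1.52 ± 0.40), Bpifb4 of nasal glands (-4.21 ± 0.99) and Tjp1 of epithelial junctions (-0.64 ± 0.18) fell. With the class I share as covariate Aqp5 was at 0.05 and did not pass, so its sign changed without showing an opposite difference. Trpc2 (2.78 ± 0.81) and Calr4 (3.86 ± 1.20) of the vomeronasal list were higher adjusted over the list alone.

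The genes with the smallest p-values included Ccdc173 (1.19 ± 0.16) and Ccdc191 (1.03 ± 0.15), coiled-coil proteins, hexokinase Hk2 (1.64 ± 0.25), the transcription factor Foxp1 (0.75 ± 0.12), Efcab2 (0.68 ± 0.11), the copper chaperone Atox1 (1.09 ± 0.17), Taf15 (0.54 ± 0.09), Gpr171 (2.02 ± 0.33) and Dnajb2 (0.53 ± 0.09), all of which rose. Olfr224, an olfactory receptor with 0 counts in all OVA libraries, was at 7.90 ± 2.80 CPM in CSJ300, at least 62.8-fold higher than a floor of 3 counts in the OVA library of smallest effective size (OVA 1). The corresponding genes that fell were Rbl2 (-0.57 ± 0.08), Pnpla8 (-0.52 ± 0.08), Arl1 (-0.74 ± 0.11), Etfdh (-0.68 ± 0.10), Acat1 (-0.64 ± 0.10), Ace (-2.31 ± 0.35), Asah1 (-0.49 ± 0.08), Slc25a16 (-0.64 ± 0.10), Adgrl4 (-2.51 ± 0.40) and Dpyd (-2.20 ± 0.35). Acat1 and Etfdh are mitochondrial enzymes and Adgrl4 is a receptor of endothelial cells. In the 15 lists of type 2 cytokines, glucocorticoid response, extracellular matrix, cell cycle, T cells, eosinophils, neutrophils, macrophages, vomeronasal neurons, ciliated cells, squamous epithelium, skeletal muscle, bone, erythroid cells and fat cells, 0 members passed over all genes.

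In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the smallest adjusted p was 0.0275, shared by the leading genes, and Nqo1 had an adjusted p of 0.0399, Muc5b 0.0573 and Muc5ac 0.136. Unadjusted p lay under 0.05 for 4820 genes, DESeq2 called 3065 and limma-voom 6181, and the libraries of both groups did not overlap for 37.0% of genes, where chance gives 10%. Camera called 8 of 31 lists with the preset correlation, including endothelial cell (adjusted p = 1.62e-07), Schwann and myelin (adjusted p = 0.000294), aryl hydrocarbon receptor (adjusted p = 0.000147), NRF2 (adjusted p = 0.000147) and MHC class II (adjusted p = 0.000187). None passed with an estimated correlation (adjusted p = 0.433 for the first 3 and 0.909 for NRF2 and MHC class II). Fry called the first 3 (adjusted p = 0.00737 each). Leaving out OVA 2, OVA 3, CSJ300 1, CSJ300 2 or CSJ300 3 left 0 genes passing, while the log2 differences of the 1497 genes were at median ratios of 0.944 to 1.02 to those with all libraries. A covariate for vomeronasal receptor counts left 0 passing at a median ratio of 0.894, with all 1497 genes in the same direction and a median SE of 0.497 in place of 0.384. A covariate for the class I share left 0 passing at a median ratio of 0.384, with 1399 in the same direction and a median SE of 0.587. Without OVA 1, 1127 passed, and the Nqo1 call ended in each of these fits and with the replicate number as a block. With library size alone as the scaling, which moved the median of all genes by 0.144 on the log2 scale, 871 genes passed and 50.7% of them rose (442 against 429), against 32.6% with TMM factors.

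**Figure D2:**
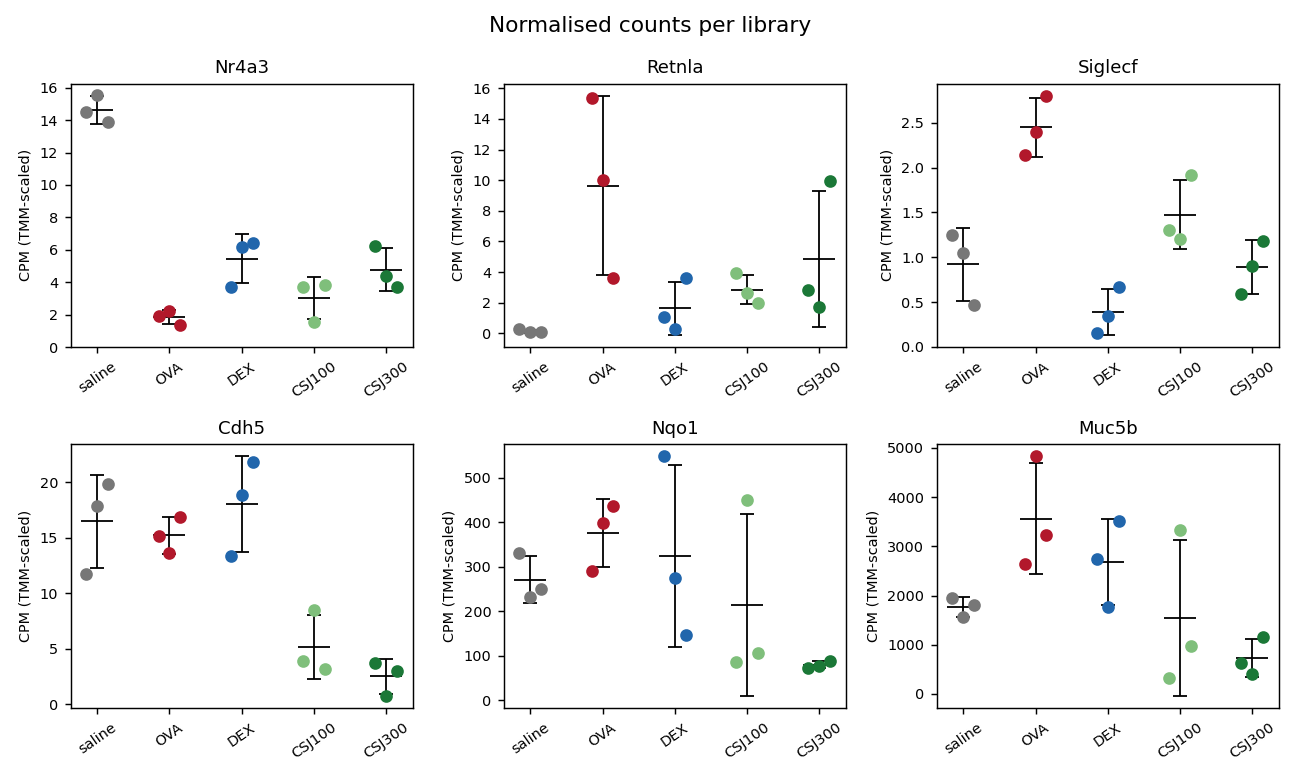
Levels of Nr4a3, Retnla, Siglecf, Cdh5, Nqo1 and Muc5b in each library (CPM, vertical axis) by group (horizontal axis); points are libraries and lines the mean with its SD, n = 3. Nr4a3 fell from 14.6 CPM in saline to 1.83 CPM in OVA, Cdh5 from 15.2 CPM in OVA to 2.49 CPM in CSJ300, and Nqo1 from 376 to 80.0 CPM, whereas Muc5b at 735 CPM in CSJ300 and Siglecf at 0.387 CPM in DEX did not pass over all genes.

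The doses were compared directly to ask whether CSJ300 differed from CSJ100. No gene passed. The genes with the smallest p-values were Fgl2, a secreted fibrinogen-like protein (1.27 ± 0.22), Ppic (2.63 ± 0.47) and Dlx3 (3.44 ± 0.63) above CSJ100 and Gbx2 (-4.12 ± 0.85) below it. Gbx2 was at 0.302 ± 0.18 CPM in CSJ100 and at 0.0123 ± 0.0213 CPM in CSJ300, below the floor of 3 counts. The size of its difference is therefore uncertain. Olfr748 and Prss56 had 0 counts in all CSJ300 libraries and were at 0.324 ± 0.203 and 0.272 ± 0.149 CPM in CSJ100, so that CSJ300 was at least 2.57-fold and 2.16-fold lower than CSJ100 when set at 3 counts in its library of smallest effective size (CSJ300 1). Nqo1 was at -1.42 ± 0.57, Muc5b at -1.07 ± 0.65, Muc5ac at 0.44 ± 1.08 and Clca1 at 2.26 ± 1.36. Between CSJ300 and CSJ100, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p = 0.406), with 1523 genes at an unadjusted p under 0.05, while DESeq2 called 114 and limma-voom 0. Without CSJ100 1, 2 genes passed. Camera called 13 of 31 lists with the preset correlation, among them MHC class II (adjusted p = 5.80e-08). None passed with an estimated correlation (adjusted p = 0.702 for that list) or with fry. The MHC class II list overlapped between both groups, as CSJ100 3 (mean log2 CPM of 4.61) lay above CSJ300 1 (3.56). The same held for B and plasma cells (4.57 against 2.48) and T cells (1.5 against -0.76).

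The slope over 0, 100 and 300 mg/kg called 379 genes that rose and 732 that fell. It rests mainly on OVA and CSJ300 and does not show a graded response. CSJ100 against OVA and CSJ300 against CSJ100 called 0 genes each. Without CSJ100 1, 2 or 3 the slope called 1402, 1370 and 1247 genes, and without any CSJ300 library 0. Per 100 mg/kg, Hk2 rose by 0.50 ± 0.08, Gpr171 by 0.63 ± 0.10, Ccdc173 by 0.37 ± 0.05, Ccdc191 by 0.32 ± 0.05 and Foxp1 by 0.24 ± 0.04. Arl1 changed by -0.23 ± 0.04 per 100 mg/kg, Etfdh by -0.21 ± 0.03, Rbl2 by -0.17 ± 0.03, Pnpla8 by -0.16 ± 0.03 and Asah1 by -0.16 ± 0.03. Nqo1 fell (-0.74 ± 0.20, but 0.05 with the class I share as covariate), and Muc5b (-0.73 ± 0.23) and Muc5ac (-0.79 ± 0.38) did not pass. The endothelial list had 7 of 10 members that fell and 10 adjusted over the list alone, and the Schwann and myelin list 5 of 8 and 7. The aryl hydrocarbon receptor list had 3 of 11 that fell and 7 adjusted over the list alone.

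For the slope, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p-values from 0.0366 upward, 0.0483 for Nqo1 and 0.075 for Muc5b. Fry called these 3 lists (adjusted p = 0.0103 each) and camera 8 with the preset correlation, but none with an estimated correlation (adjusted p = 0.399 for each of the 3). Unadjusted p lay under 0.05 for 4473 genes, DESeq2 called 2605 and limma-voom 5375. The slope called 0 genes without OVA 2, OVA 3, CSJ300 1, CSJ300 2 or CSJ300 3, and 0 with the replicate number as a block or a covariate for vomeronasal receptors or the class I share, where the slopes of the 1111 genes were at median ratios of 0.995, 0.891 and 0.397. With library size alone, 599 genes passed and 55.8% of them rose (334 against 265), against 34.1% with TMM factors, and with only the 3 groups in the fit 252 passed (174 against 78).

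CSJ300 was also set against DEX, as the extract at its higher dose against the reference drug. Of 10 MHC class II genes, 7 rose over all genes and 10 adjusted over the list alone. The corresponding counts were 5 and 7 of 9 B and plasma cell genes, 3 and 9 of 16 T cell genes and 2 and 7 of 9 eosinophil genes. The T cell list of CSJ300 1 (mean log2 CPM of -0.76) lay within the DEX range (-1.63 to 0.02). Endothelial genes fell (9 of 10 over all genes and 9 adjusted over the list alone), as did 11 of 33 NRF2 genes (14 adjusted over the list alone), 7 of 21 glucocorticoid genes (8), 4 of 5 fat cell genes (4) and 4 of 11 aryl hydrocarbon receptor genes (9). Genes that rose with the smallest p-values were Ccdc173 (1.37 ± 0.16), Efcab2 (0.91 ± 0.11), B3gnt4 (1.54 ± 0.19), the cell cycle subunit Cks2 (1.46 ± 0.20) and Ccdc191 (1.12 ± 0.15). Those that fell were the lysosomal ceramidase Asah1 (-0.62 ± 0.08), Ace (-2.73 ± 0.36), Osgin1 (-1.29 ± 0.18), the Golgi mannosidase Man2a1 (-1.69 ± 0.25) and the oncostatin M receptor Osmr (-1.75 ± 0.26). Fkbp5 fell by 1.46 ± 0.44 and Nqo1 by 2.02 ± 0.58, while Muc5b (-1.87 ± 0.67) and Muc5ac (-1.76 ± 1.11) did not pass. With the class I share as covariate Nqo1 was at 0.30 and did not pass, so its sign changed without showing an opposite difference.

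This comparison called 2279 genes, 1114 higher and 1165 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0112), and 6021 had an unadjusted p under 0.05. Fry called 6 of 31 lists, namely endothelial (adjusted p = 0.00773), aryl hydrocarbon receptor (0.0179), fat cell (0.019), NRF2 (0.0228), MHC class II (0.0316) and eosinophil (0.0466). Camera called 17 with the preset correlation and none with an estimated correlation (adjusted p = 0.603 for each of these 6). Left-out libraries moved the count to 0 without DEX 2 or CSJ300 2, 77 without DEX 3, 556 without CSJ300 1 and 1134 without CSJ300 3, and covariates to 296 for olfactory neurons, 1159 for vomeronasal receptors and 0 for the class I share, at median ratios of the log2 differences of 0.777, 0.97 and 0.603. With library size alone, which moved the median of all genes by 0.141 on the log2 scale, 1065 genes passed and 71.5% of them rose (761 against 304), against 48.9% with TMM factors.

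**Figure D3:**
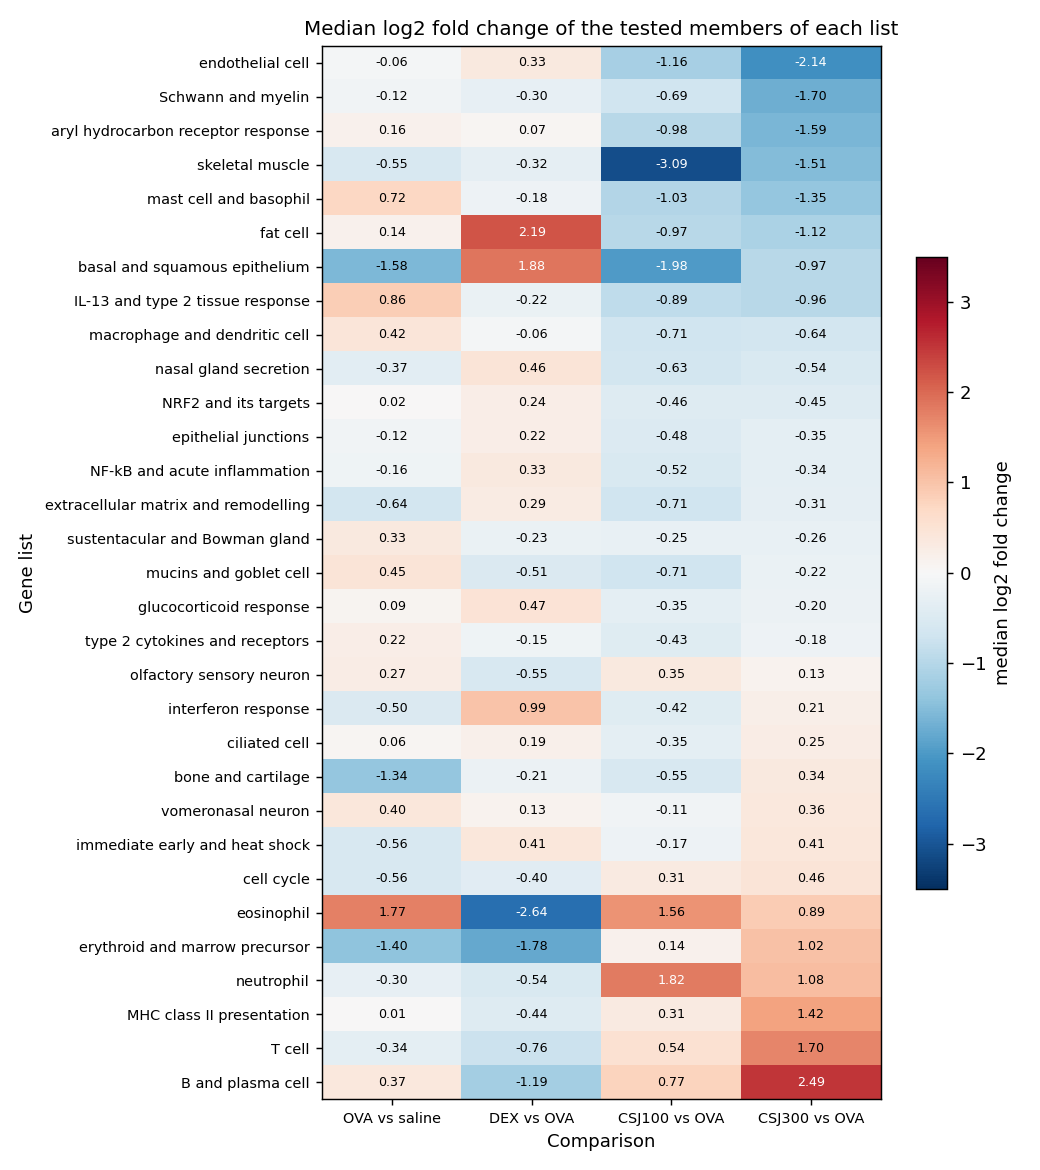
Heat map of the median log2 difference (colour scale) of each fixed gene list (vertical axis) in OVA against saline and in DEX, CSJ100 and CSJ300 against OVA (horizontal axis), each from 3 libraries per group. The endothelial list has medians of -1.16 in CSJ100 and -2.14 in CSJ300, the eosinophil list 1.77 in OVA against saline and -2.64 in DEX, and no list passed with an estimated correlation.

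Whether treatments moved genes against the OVA changes, or alike, was measured across the 17873 genes, which are not independent replicates. The Pearson correlation of the OVA-against-saline differences with the treatment differences was 0.036 for DEX, -0.293 for CSJ100 and -0.134 for CSJ300. Simulated unchanged groups that shared their OVA libraries gave -0.492, -0.492 and -0.498. Covariances were 0.017, -0.163 and -0.092 against simulated values of -0.143, -0.143 and -0.145, so the differences were 0.159, -0.019 and 0.054. The SD of simulated r was 0.017 to 0.018, while a left-out library took r for DEX to values from -0.46 to 0.147. The simulated values thus do not cover the variation between these libraries, and differences from them cannot be told from it. The sign of r turned for DEX without saline 1 (-0.177), OVA 1 (-0.46), OVA 3 (-0.312) or DEX 1 (-0.069), and without saline 1 for CSJ100 (0.165) and CSJ300 (0.162). Nr4a3, the single OVA call, rose in CSJ300 against OVA, and both calls rest on the same 3 OVA libraries.

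Differences from OVA correlated at 0.603 between CSJ100 and CSJ300 (simulated 0.496), 0.314 between DEX and CSJ300 (simulated 0.499) and -0.255 between DEX and CSJ100 (simulated 0.493). Their covariances were 0.643, 0.278 and -0.183 against simulated 0.144, 0.144 and 0.142, differences of 0.499, 0.134 and -0.325. Without OVA 1 these correlations were 0.711, 0.579 and 0.155, and without CSJ100 1 the doses correlated at 0.442. No overlap of calls could be counted, since DEX and CSJ100 called 0 genes by edgeR (1287 and 2987 at an unadjusted p under 0.05, 50 and 577 by DESeq2). The 3 OVA libraries were too few to split, so part of any excess may come from the shared controls. Simulated r had an SD of 0.012 to 0.014, less than the shifts made by left-out libraries. Differences from simulated values thus cannot be told from variation between libraries.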

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

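The CSJ300 and DEX groups of the OVA model differed by a test of the difference itself, the contrast of both groups. It called 2279 genes with edgeR's quasi-likelihood test. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split gave 2279 genes and the highest other 0, and 1 split was as large, the real one. The class I share of olfactory receptor counts differed too (2.84% in CSJ300, 20.8% in DEX). With this share as covariate edgeR called 0 genes (755 at an unadjusted p under 0.05), at a median ratio of 0.603 of the log2 differences, so the difference is between groups and was not shown to be one of treatment effects.

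The named genes with a difference between CSJ300 and DEX were Ccdc173 (log2 difference 1.37), Efcab2 (0.91), B3gnt4 (1.54), Cks2 (1.46) and Ccdc191 (1.12), which were higher in all 3 CSJ300 libraries than in all 3 DEX libraries. Asah1 (-0.62), Ace (-2.73), Osgin1 (-1.29), Man2a1 (-1.69) and Osmr (-1.75) were lower in all 3. The naming rule required that the groups not overlap, which chance gives for 10% of genes and which held for 40.4% of all tested genes here.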

How the results depend on the processing

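The GC and length correction and the covariates for vomeronasal receptors and class I share were chosen after the data were seen. Named genes kept their side of the threshold in 7491 cases over all alternatives, lost the call in 545, gained one in 168 and reversed in 7. For lists these numbers were 1867, 301, 92 and 3. Most named genes were not called in the main fit, and a gene called in neither fit counts as kept, so 7491 does not measure how calls held. Among named genes the class I covariate ended 64 calls and reversed 7, the vomeronasal covariate ended 62, and fits with a library left out ended 344. A change of sign in a gene or list called in neither fit was not counted as a reversal. An estimated correlation ended 94 list calls and fry 82. The 1497 genes called in CSJ300 against OVA kept their direction under all alternatives in which they were tested (1450 of them with the stricter filter, 1484 with only both groups) except the class I covariate, where 1399 did. They were picked by their differences in these same libraries, which the alternatives fit again, so a kept direction is no independent support. Except where fewer libraries or genes were tested, the cause of a change was not tested. Depth limits calls on genes such as Il4, Il5 and Il13, which lay below the filter.

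OVA against saline gave 1 gene and 0 to 0 with a library left out; it gave 0 with RLE factors, library size alone, only the groups compared, the replicate block, the muscle covariate, the GC correction and the vomeronasal covariate, 4 with the olfactory covariate and 2 with the class I covariate. DESeq2 called 23 and limma-voom 6.

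DEX against OVA gave 0 genes, 50 with DESeq2, 3010 with limma-voom and 0 to 40 with a library left out. CSJ100 against OVA gave 0, 577 with DESeq2, 2541 with limma-voom, 1 with the replicate block and 0 to 1159 with a library left out. CSJ300 against CSJ100 gave 0, 114 with DESeq2 and 0 to 2.

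CSJ300 against OVA gave 1497 genes, 871 with library size alone, 3065 with DESeq2, 6181 with limma-voom, 2408 with only both groups, 2320 with the olfactory covariate, 0 with the vomeronasal and 0 with the class I covariate (median ratios of the log2 differences 0.894 and 0.384), 972 with an absolute log2 difference of at least 1, and 0 to 1127 with a library left out.

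CSJ300 against DEX gave 2279, 1065 with library size alone, 4462 with DESeq2, 7735 with limma-voom, 296, 1159 and 0 with the olfactory, vomeronasal and class I covariates, 1193 with the log2 threshold, and 0 to 2373 with a library left out.

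The slope gave 1111, 599 with library size alone, 2605 with DESeq2, 5375 with limma-voom, 252 with only the 3 groups, 0 with the replicate block, 2039, 0 and 0 with the same covariates, 325 with the log2 threshold, and 0 to 1402 with a library left out.

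With the class I covariate, Gsta2 (0.01), Nqo1 (0.18), Cyp1a1 (0.25), Ier2 (-0.09) and Aqp5 (0.05) changed sign in CSJ300 against OVA, Nqo1 also against DEX (0.30) and in the slope (0.05). These were counted as reversals, but no gene passed in these fits, so opposite differences are not shown. The neutrophil list reversed in OVA against saline without saline 3 (camera, adjusted p = 0.584, range 3.14e-05 to 0.584 over left-out libraries). The nasal gland list reversed in DEX against OVA without OVA 3 (adjusted p = 0.896, range 0.000203 to 0.896), and the T cell list in CSJ100 against OVA without CSJ100 3 (adjusted p = 0.0252, range 0.0252 to 0.881).

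With a library left out, correlations of the OVA differences with those of DEX, CSJ100 and CSJ300 ranged from -0.46 to 0.147, -0.54 to 0.165 and -0.444 to 0.162. Those between DEX and CSJ100, DEX and CSJ300 and both doses ranged from -0.327 to 0.155, 0.242 to 0.579 and 0.442 to 0.711.

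The replicate numbers were not taken to pair the samples: over 30 pairs of same-numbered libraries the correlation of deviations ran from -0.52 to 0.46, with 13 over 0.1. With them as a replicate block, CSJ300 against OVA gave 1214 genes.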

Other observations

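The tests of connective tissue, of lower NRF2 activity, of the class I share as a covariate and of both clock gene explanations were chosen after the results were seen. The correction for GC content and length was added after the data were seen. The vomeronasal test uses DEX libraries and genes picked by their values, and the Nqo1 test uses Acsm4, chosen after its values were seen.

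Zonal genes of the olfactory epithelium passed in CSJ300 against OVA for Acsm4 and Nrp2, and for neither in CSJ100 against OVA. Acsm4, an enzyme of the dorsal olfactory epithelium (chromosome 7, 119690026 to 119714565), fell from 1160 ± 331 CPM in OVA to 96.4 ± 20.8 CPM in CSJ300 (SD, n = 3; log2 difference -3.58 ± 0.78). In CSJ100 it was at 97, 1200 and 201 CPM (adjusted p = 0.383 by edgeR), and in DEX at 463 ± 244 CPM, which did not pass either. Nrp2, a guidance receptor of ventral olfactory axons, rose from 47.7 ± 6.66 to 92.4 ± 20.5 CPM. Ncam2, a cell adhesion molecule of ventral neurons, was at 22.2 ± 10.3 CPM in OVA and 55.5 ± 8.75 CPM in CSJ300 and passed at neither dose. These 3 genes were chosen after their values were seen.

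Ribosomal precursor RNA, counted as Rn45s, was at 171 ± 26 CPM in saline, 135 ± 5.12 in OVA and 140 ± 28.7 in DEX, and at 275 ± 57.9 in CSJ100 and 309 ± 112 in CSJ300. All 6 extract libraries were at 208 CPM or more and all others at 188 CPM or less. Rn45s was called in CSJ300 against OVA (log2 difference 1.20 ± 0.25, adjusted p = 0.0275 by edgeR) and against DEX (adjusted p = 0.0208) and in the slope (adjusted p = 0.0366), beside the other genes called there, and not in CSJ100 against OVA (adjusted p = 0.209). Malat1, a nuclear long non-coding RNA, was at 2140 ± 994 CPM in saline, 1690 ± 235 in OVA, 2890 ± 750 in CSJ100 and 3590 ± 916 in CSJ300 and did not pass; saline 2, at 3290 CPM, lay above CSJ300 1 (3010), CSJ300 3 (3110) and CSJ100 3 (2020). A list of 13 nuclear RNAs had a median of 0.78 in CSJ100 and 0.46 in CSJ300 against OVA (limma's fry, adjusted p = 0.0365 and 0.0817 over 21 tests; camera, adjusted p = 0.187 and 0.426 with an estimated correlation) and of 0.49 and 0.35 against saline (adjusted p = 0.237 and 0.345 over 12 tests). Both genes and the list were chosen after their values were seen.

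The first pattern is the set of genes that changed in CSJ300 against OVA. Correction for GC content and length left the differences at a median ratio of 0.992, with 1466 genes called and 1191 of the 1497 among them, which argues against that trend as the cause. Vomeronasal tissue in the piece is argued against as the source of the medians of both gene sets, since DEX 1 and DEX 2 held as many vomeronasal receptor counts. They held at most 0.043 of the CSJ300 median difference of the genes that rose (lowest -0.11, CSJ300 median 1.07). For the genes that fell this share was at most 0.21 (lowest 0.14, median -1.87). The sets were picked in CSJ300, and DEX 1 and DEX 2 also carry the drug, so single genes may still follow that tissue. A smaller share of connective tissue with its vessels as the source of the fall stays open. The matrix list had a median of -0.31 over 18 genes, with members from -2 to 0.84, against -2.14 over 10 endothelial genes. The two-sided permutation p of 0.00041 shuffles genes, which are not independent replicates. Medians of the Schwann and myelin (-1.70), mast cell (-1.35) and fat cell (-1.12) lists were low with the vessels, while bone and cartilage was at 0.34. A smaller share of dorsal olfactory epithelium in the piece may contribute and cannot be told apart from the extract: with the class I share as covariate the differences had a median ratio of 0.384 (median SE 0.587 in place of 0.384) and 0 genes passed. At the fixed dose of CSJ100 the fall followed the class I share: the genes that fell had medians of -1.58, -0.12 and -1.24 against OVA in CSJ100 1, 2 and 3, with shares of 2.99%, 23.1% and 4.29%, and the genes that rose 0.72, 0.39 and 0.68. The fit rests on that group, which held 79% of the covariate's variance within groups. Without CSJ100 2 the median ratio was 0.643 (0.285 to 0.415 without any other library), and a piece in which the extract acted less would give the same values, which keeps this open.

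The second pattern is the fall of Nqo1, an enzyme of dorsal olfactory neurons and a target of NRF2. A candidate explanation is a smaller dorsal zone in the CSJ300 pieces, since the dorsal gene Acsm4 fell by 3.58 and the class I share by 3.17 on the log2 scale, each more than the -2.23 of Nqo1. Lower NRF2 activity stays open: the other 32 members of the NRF2 list had a median of -0.43, and 27 of them were lower, but a median far below the change of Nqo1 over members that went both ways decides nothing. An effect of the extract on the dorsal epithelium itself was not tested and stays open too.

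The third pattern concerns clock genes, which differed between OVA and saline. The Per side (Per1, Dbp and 8 others) had a median of 0.60 (limma's fry, adjusted p = 0.00218) and the Arntl side of 4 genes -0.43 (adjusted p = 0.0116), opposite directions such as another hour of collection gives, so time of day may account for it. By camera with an estimated correlation the Per side passed (adjusted p = 0.0288 over 21 tests) and the Arntl side did not (adjusted p = 0.0714), and collection times were not given. OVA exposure as such cannot be told apart. In the other groups given OVA 4 of 6 tests went the same way with an adjusted p under 0.05, but all 6 share the saline libraries with the OVA comparison, so a chance shift of saline would give this too and the count decides nothing. The 4 were the Arntl side in DEX (-0.35), CSJ100 (-0.41) and CSJ300 (-0.46) and the Per side in DEX (0.87), but not the Per side in CSJ100 (0.22, adjusted p = 0.246) or CSJ300 (0.17, adjusted p = 0.345). Against DEX, 8 of 10 genes of the Per side fell in CSJ300 (adjusted p = 0.0714 for the list by camera with an estimated correlation). Against OVA, the Per side had medians of 0.33 in DEX, -0.38 in CSJ100 and -0.46 in CSJ300 (fry, adjusted p = 0.0195, 0.0172 and 0.0129), and none passed with an estimated correlation (adjusted p = 0.0866, 0.187 and 0.187).

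Other splits of the same samples show how far the counts of calls can come from grouping alone. For the slope, 1 of 100 splits, the real one, gave as many genes (1111), a share under 0.05, and the highest other gave 134. The labels do not say whether the libraries of a group came from separate mice, so this share does not exclude chance differences between mice. It concerns the count of calls and does not show a graded dose response. The 10 splits of each other comparison are too few for a share under 0.05. They gave for OVA against saline 1 gene in the real split and 449 in the highest other (2 splits as large), for DEX against OVA 0 and 50 (10 as large), for CSJ100 against OVA 0 and 1 (10), for CSJ300 against OVA 1497 and 0 (1), and for CSJ300 against CSJ100 0 and 94 (10). The split with 449 set saline 1, OVA 2 and OVA 3 against saline 2, saline 3 and OVA 1, which points to a structure of the samples other than their groups. Olfactory receptor counts were 2998, 2770 and 2576 CPM of total counts in the first set and 769, 1424 and 1341 in the second. This split thus follows the olfactory receptor counts of the libraries. The split with 50 set OVA 1, DEX 1 and DEX 2 against OVA 2, OVA 3 and DEX 3, and DEX 1, DEX 2 and OVA 1 held the highest vomeronasal receptor counts of their groups (828, 509 and 50.9 CPM of total counts).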
